A study of Homo sapiens with 4 samples.

How the data were processed

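Gene expression was measured in CP70sps cells, spheres selected from the Cp70 ovarian cancer line by Hoechst exclusion and grown in low-attachment plates in serum-free medium with growth factors. Cells were exposed to 3 µM niclosamide for 0, 2, 4 or 6 h. Per the labels, total RNA was treated with DNase, and biotin-labelled cRNA was hybridized to Illumina bead arrays of 48803 probes. The 4 arrays form 4 groups of 1 array each, set by the time point in the labels, so no time point has a replicate.

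The deposited non-normalized values are an intensity per probe and array, made with BeadStudio per the submitters' processing notes, with no version or settings stated. The deposited detection values are, per the file headers, a p-value of each probe against the negative controls of its array, and they fall on multiples of the inverse of 759. The processed intensity values of the authors were checked against the non-normalized ones: they equal a quantile normalization on the linear scale within 1.46% at every probe, with no background subtraction. Of the probes, 27578 have 1 gene symbol in the probe table used, 13 have several and 21212 were left unnamed and were used only for normalization and for a count of their own. The named probes carry 18665 symbols. Of 27591 probes in that table, 27541 have an Entrez identifier held by the RefSeq table and 50 do not. The RefSeq table is of another assembly than any the deposited values name, so no positions are given.

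Non-normalized intensities were processed with limma 3.58.1 in R 4.3.3. Background was removed by the normexp model with negative control levels inferred from the detection p-values, an offset of 16 was added, and log2 values were quantile normalized over the 4 arrays (the neqc method). A probe was called detected at a detection p under 0.01. Each gene was represented by the probe with the highest mean log2 value among its probes detected on at least 1 array, which left 9771 genes. The number of arrays limits the precision of every value. The detected share of probes was 28.3% at 0 h, 28.7% at 2 h, 29.6% at 4 h and 28.3% at 6 h.

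Each later time was compared with 0 h by the log2 fold, and genes detected on both arrays were counted at a fold of at least 2 with no test. Genes detected on 1 of the 2 arrays gave a bound, taken against the lowest detected level of the other array. As a yardstick, the robust spread of log2 differences between 6 h and 4 h, in 20 bins of expression, was used to simulate 4 unchanged arrays 100 times. The spread of that pair, 0.230, is the second narrowest of the 6 pairs, so the simulation holds less noise than the comparisons with 0 h, where it was 0.387, 0.329 and 0.422. A linear trend over hours was fitted with limma (eBayes with an intensity trend, 2-sided, Benjamini-Hochberg adjusted p under 0.05 over 9771 genes), with 2 residual degrees of freedom and 9.60 prior degrees of freedom. The residual of that fit mixes departures from a line with the spread of arrays, so early or transient changes are not called.

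Fixed gene lists, 39 in all, were summarised by the median log2 difference of the members detected on at least 1 array, by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and by the members at least 1.5-fold higher or lower. A list of at least 3 measured members stood apart when its percentile was under 2.5 or over 97.5. The lists were: integrated stress response (ATF4 and CHOP targets), synthesis of serine, glycine, proline and single-carbon units, aminoacyl-tRNA synthetases, unfolded protein response of the endoplasmic reticulum (XBP1 and ATF6 targets), glycolysis and lactate export, hypoxia-inducible factor targets, nuclear-encoded subunits of oxidative phosphorylation, tricarboxylic acid cycle and pyruvate dehydrogenase, mitochondrial biogenesis, import and proteostasis, NRF2 targets, antioxidant and glutathione enzymes, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation, nucleotide synthesis, Wnt and beta-catenin targets, Notch targets and receptors, NF-kappaB targets, STAT3 targets, p53 targets, immediate early genes, heat shock response, metallothioneins and zinc export, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, ribosome biogenesis, cytosolic ribosomal proteins, autophagy and lysosome (TFEB targets), BCL2 family, interferon-stimulated genes, tumour-initiating cell and pluripotency markers, epithelial, mesenchymal, leukocyte, endothelial, fibroblast and erythroid markers, and reference genes.

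Named genes followed a fixed rule. It took the 10 largest increases and the 10 largest decreases at each time among genes detected on both arrays, up to 5 bounds of at least 2-fold in each direction at 6 h, and up to 4 members of each list with the largest difference at 6 h and up to 4 at 2 h. MYC, CCND1, AXIN2, ABCG2, CD44, KIT, PROM1, ALDH1A1, ATF3, DDIT3, TRIB3, CHAC1, TXNIP, HMOX1 and STAT3 were always named where measured. Lists, rule, tests, thresholds and the first set of alternatives were chosen before the data were examined.

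Those alternatives were no background correction, scaling each array to 1 median in place of quantile normalization, the processed values of the authors, an offset of 50, no detection filter, detection on all 4 arrays, the median over the probes of a gene, eBayes without an intensity trend, and leaving out each array from the trend. Chosen after seeing the data were normalizing only the 2 arrays compared, counting genes with every one of several probes past the fold, comparing 6 h with 2 h, and correlating the 2 probes of a gene. That correlation used the 1710 genes with exactly 2 probes detected on all arrays, with intervals from 1000 bootstrap resamples of genes, and was repeated on other scalings and on probes with a mean log2 of at least 10. Variance shared by the probes was their covariance.

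The steps were tested on data simulated with the same narrow spread, with changes added to 100 genes at each size among 9771. Past 2-fold at 6 h, 47% of 2-fold and 100% of 4-fold changes were recovered with 1 unchanged gene counted, and the trend test recovered 48% and 100% with 5 unchanged genes called. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No samples were left out.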

Results

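CP70sps cells are sphere-forming cells taken from the Cp70 ovarian cancer line by their ability to exclude the dye Hoechst, and the labels call them ovarian tumour-initiating cells. They were exposed to 3 µM niclosamide, an anthelmintic drug known to uncouple mitochondrial respiration from ATP synthesis, and total RNA was hybridized to a human Illumina bead array of 48803 probes. One array was run at each of 0, 2, 4 and 6 h, which makes 4 arrays with no replicates at any time. The 0 h array was the only untreated reference, and 0 arrays came from cells kept to a later time without the drug. Probes with a detection p under 0.01 numbered 13797 at 0 h, 14010 at 2 h, 14461 at 4 h and 13827 at 6 h, between 28.3% and 29.6% of all probes. The median signal was 66.0, 62.4, 63.2 and 66.0 intensity units in the same order, and the lowest detected signal lay between 107 and 121 units. In all, 9771 genes were detected on at least 1 array and 9001 on all 4. The comparisons follow the labels and ask which transcripts differed after 2, 4 and 6 h of exposure. With 1 array per time, folds carry no error and no p-value, and the number of arrays limits their precision. The percentiles given for gene lists describe these arrays only.

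After 2 h, the largest single increases were those of PACS1, which encodes a trans-Golgi sorting protein, at 3.93-fold, and of the protein kinase gene DYRK1B at 3.86-fold. IRF1, the gene of an interferon-regulated transcription factor, was 4.20 times lower, and the interferon-inducible IFI6 was lower by a log2 difference of -1.79, although the list of 15 interferon-stimulated genes did not stand apart, with a median of -0.16 (percentile 11.6 among 10000 random lists matched on expression) and 1 member at least 1.5-fold lower. The list of metallothioneins and zinc export had a median of 0.48 (percentile 99.0) over only 4 measured genes, of which the zinc-sensing transcription factor gene MTF1, at 0.99, was the 1 at least 1.5-fold higher, and SLC30A1 read 0.37 and -0.14 on its probes. The 22 measured genes of G1/S and DNA replication had a median of -0.32 (percentile 0.14), with 5 at least 1.5-fold lower and 17 neither, including the replication licensing factor CDT1 at -1.36. The integrated stress response genes DDIT3, which encodes the stress-induced transcription factor CHOP, and CHAC1, which encodes a glutathione-degrading enzyme, were higher by 0.73 and 0.70 on the log2 scale, under 2-fold, and their list did not stand apart at 2 h, with a median of 0.03 (percentile 71.0).

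Counted over the 9120 genes detected on both arrays, 123 were at least 2-fold higher at 2 h (1.35%) and 118 at least 2-fold lower (1.29%). Scaling each array to 1 median in place of quantile normalization changed this split to 189 higher and 83 lower. In simulated unchanged arrays with the spread seen between 4 h and 6 h, a mean of 0.24 genes passed upward and 0.41 downward, with at most 3 in either direction. That spread, 0.230, is narrower than the 0.387 between 2 h and 0 h, and the simulation leaves out the shifts of single probes described further on. Among the other large increases were SSBP3 at 1.90, PPDPF at 1.88, BORCS8-MEF2B at 1.75, PIANP at 1.70, SCAF1 at 1.70, CEP170B at 1.68 and the kinesin light chain gene KLC2 at 1.69. Large decreases included SIPA1 at -1.62, the protease gene PRSS8 at -1.62, FRS3 at -1.57, SH3GL1 at -1.56, UBE2J2 at -1.55, SLC38A4 at -1.54, CEP85 at -1.50 and LRRC56 at -1.49. Second probes of the same gene often gave another value. A second DYRK1B probe read 1.30 and a second KLC2 probe 1.85, but a second SSBP3 probe read 0.56, a second IFI6 probe -0.44, a second SIPA1 probe 0.52 and a second UBE2J2 probe 0.41. Of 2063 genes with several detected probes, 13 passed the fold upward and 20 downward by their brightest probe, and every probe had the same sign in 11 and 7 of these. Every probe passed the fold in 3 genes upward and 0 downward. The 3, chosen after their values were seen, were DYRK1B, MEIS3 and PRRC2A.

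After 4 h, DDIT3 and CHAC1 were 1.20 and 1.24 above 0 h, and the integrated stress response list reached a median of 0.28 (percentile 99.9). Targets of the hypoxia-inducible factor, which switches on genes for angiogenesis and anaerobic metabolism, had a median of -0.41 (percentile 0), with the vasodilator peptide gene ADM at -0.93 and the angiogenic growth factor gene VEGFA at -1.05 on its brightest probe and -0.77 on a second, which had read -1.47 and -0.85 at 2 h. Mitotic genes were higher, with a median of 0.34 (percentile 100), and replication-dependent histone genes were lower, with a median of -0.53 (percentile 0) and the linker histone gene H1-2 at -1.29. Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.17 (percentile 0).

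At 4 h, 20 of 9217 genes were at least 2-fold higher and 39 at least 2-fold lower. Median scaling moved the median of all genes to 0.156 at 4 h, from 0.0134, and gave 66 genes higher and 14 lower. The simulated unchanged arrays, without shifts of single probes, gave means of 0.47 and 0.40 genes, with at most 3 in either direction. The largest increases besides CHAC1 and DDIT3 were those of DYRK1B at 1.29, WDR81 at 1.24, TTYH3 at 1.21, the JNK scaffold gene MAPK8IP3 at 1.20, ZNF609 at 1.13, PLD6 at 1.11, TANC1 at 1.10 and UAP1L1 at 1.09. A second MAPK8IP3 probe read 0.24 and a second DYRK1B probe 0.33. Lower genes included the small noncoding RNA SNAR-A1 at -1.61, SPRYD3 at -1.41, S100A3 at -1.38, CDC42EP2 at -1.34, R3HCC1 at -1.34, PRSS8 at -1.26, CUEDC1 at -1.26, IRF1 at -1.25 and the Integrator subunit gene INTS1 at -1.24. SNAR-A1 stood at 0.21 at 2 h and -0.03 at 6 h. Among 2114 genes with several detected probes, the brightest probe passed in 4 upward and 6 downward, all probes had the same sign in 3 and 2 of these, and 0 genes had every probe past the fold.

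After 6 h, CHAC1 was 4.99-fold and DDIT3 4.05-fold above 0 h, followed in their list by the stress-induced transcription factor gene ATF3 at 3.10-fold, the mTORC1 regulator SESN2 at 1.52 and the secreted stress cytokine GDF15 at 1.20 on the log2 scale. Each of these genes had 1 detected probe, so no second probe checks the folds. VEGFA, ADM and the glycolytic regulators PFKFB4 and PFKFB3, whose enzymes set the level of fructose 2,6-bisphosphate, stood at -1.54, -1.27, -1.35 and -0.99. Second probes read -0.82 for VEGFA, under 2-fold, and -0.71 for PFKFB3. XBP1, the gene of a transcription factor of the unfolded protein response, was at 1.21, and a second XBP1 probe at 1.57. IRF1 was 4.79 times lower and the endothelial transcription factor gene SOX18 was 4.00 times lower. For 6 h minus 2 h they read -0.19 and -0.70, each on 1 detected probe. Notch receptors and targets, which relay signals between touching cells, had a median of -0.64 (percentile 0.13), and NOTCH1 stood at -1.06. That median is the value of the brightest probe of the ligand gene JAG2, of which a second probe read 0.66.

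Of 9044 genes detected on both arrays, 160 were at least 2-fold higher at 6 h (1.77%) and 176 at least 2-fold lower (1.95%), and median scaling gave 273 and 106. Simulated unchanged arrays, again without such shifts, gave means of 0.36 and 0.41, with at most 2 in either direction. BORCS8-MEF2B at 2.00, DYRK1B at 1.98, PACS1 at 1.84, the phosphatase gene DUSP8 at 1.83, MAPK8IP3 at 1.82, KLC2 at 1.81, PTPN23 at 1.72 and UAP1L1 at 1.70 completed the 10 largest increases with CHAC1 and DDIT3. For 6 h minus 2 h, the genes from BORCS8-MEF2B to UAP1L1 read 0.25, 0.03, -0.13, 0.53, 0.20, 0.12, 0.03 and 0.59 in that order. CDC42EP2 at -1.95, INTS1 at -1.86, R3HCC1 at -1.70, MPP2 at -1.61, UNC119 at -1.58, IFI6 at -1.56 and SIPA1 at -1.54 were among the 10 largest decreases, although second probes read 0.39 for UNC119, 0.22 for SIPA1 and -0.51 for IFI6. For 6 h minus 2 h, the genes from CDC42EP2 to SIPA1 read -0.86, -0.42, -0.34, -0.38, -0.12, 0.24 and 0.08 in that order. Genes detected on 1 of the 2 arrays gave bounds. C20orf96 was at least 3.34-fold higher, HDAC10 at least 2.90-fold, OLFM2 at least 2.28-fold, ADM5 at least 2.26-fold and ZNF687 at least 2.25-fold. Their log2 differences for 6 h minus 2 h were 0.28, 0.15, -0.41, 0.94 and 0.06 in that order, each on 1 detected probe. NIM1K was at least 2.99 times lower, HEXIM2 at least 2.14 times, H3C10 at least 2.05 times and FAHD2A at least 2.02 times. These 6 h minus 2 h differences were -1.96, -0.57, -0.62 and -0.06 in that order, each on 1 detected probe. Such bounds reached 2-fold in 12 genes upward and 4 downward at 6 h, in 11 and 5 at 2 h, and in 0 and 1 at 4 h.

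Among 2039 genes with several detected probes, the brightest probe passed at 6 h in 27 upward and 32 downward, with the same sign on every probe in 22 and 13. Every probe passed in 8 genes upward and 2 downward. Chosen after their values were seen, the 8 were XBP1, CREBRF, MAFG, DYRK1B, PRRC2A, PWWP2B, TNRC6A and NPIPA1, and the 2 were APBB3 and IKBIP. MAFG, which encodes a small partner of NRF2, read 1.23 and 1.39 on its probes, and CREBRF, a regulator of the unfolded protein response, 1.10 and 1.45. Over the 9001 genes detected on all 4 arrays, 9 were at least 2-fold higher at all 3 times and 20 at least 2-fold lower, against 0.00486 and 0.00969 for independent lists. Simulated unchanged arrays that share the 0 h array, and hold no shifts of single probes, gave means of 0.01 and 0. The 0 h array is common to the 3 comparisons and cannot be split, so part of the excess may come from it or from shifts of single probes.

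Probes of the same gene showed which differences were shared by the gene. Across 1710 genes with exactly 2 probes detected on all arrays, the log2 differences of both probes had a Pearson r of 0.0735 for 2 h minus 0 h (95% bootstrap interval 0.00886 to 0.138), 0.320 for 4 h minus 0 h (0.27 to 0.364) and 0.265 for 6 h minus 0 h (0.211 to 0.323). For 6 h minus 2 h, r was 0.638 (0.597 to 0.675). These correlations are across genes, which are not independent replicates, and 6 pairs of arrays were compared. The variance that both probes shared was 0.0118 at 2 h (0.00143 to 0.022), 0.0340 at 4 h (0.0284 to 0.0393) and 0.0485 at 6 h (0.0377 to 0.0601), whereas the unshared variance was 0.149, 0.0725 and 0.135. The robust spread of all genes was 0.387 for 2 h against 0 h, 0.329 for 4 h, 0.422 for 6 h and 0.215 for 6 h against 2 h. The larger part of the variance between the 2 h and 0 h arrays was therefore specific to single probes. The 6 h array was also compared with the 2 h array, a comparison chosen after the values were seen.

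**Figure D1:**
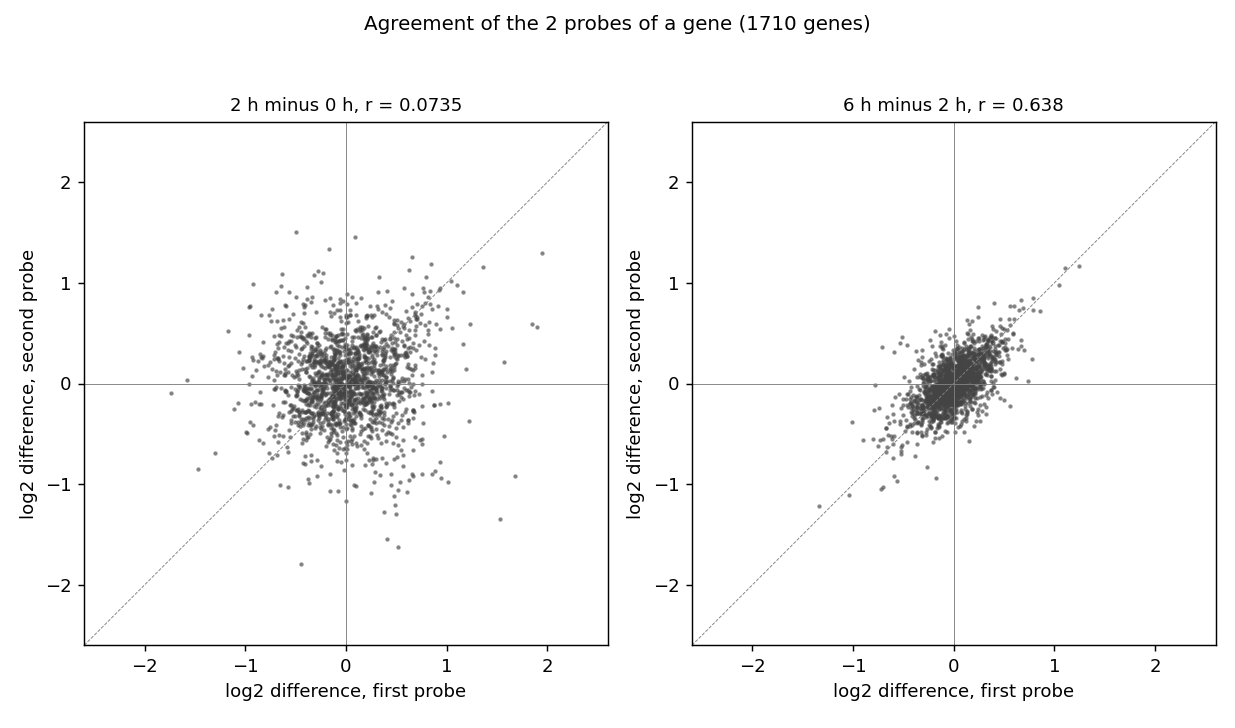
Log2 difference of the first probe (x axis) and the second probe (y axis) of 1710 genes with 2 probes detected on all arrays, 1 point per gene, for 2 h minus 0 h and for 6 h minus 2 h. The points form a round cloud in the first panel (r = 0.0735) and follow the dashed line of equal values in the second (r = 0.638).

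Against 2 h, the 6 h array again showed CHAC1 and DDIT3 as the genes with the largest increases, at 3.08-fold and 2.45-fold. The choline kinase gene CHKA followed at 1.24 on the log2 scale, ZNF165 at 1.23, the inhibin subunit gene INHBE at 1.17, XBP1 at 1.15, the stress-induced phosphatase regulator PPP1R15A at 1.08 and ATF3 at 1.06. Of these, CHAC1, DDIT3, ZNF165, INHBE, PPP1R15A and ATF3 had 1 detected probe each. The hypoxia-responsive genes ANKRD37 and HILPDA were 3.94 and 3.91 times lower. The DNA demethylase gene TET1 at -1.42, ADM at -1.28, FAM13A at -1.28, the chemokine receptor gene CXCR4 at -1.22, PFKFB3 at -1.11, CEBPD at -1.08 and the lipase inhibitor gene ANGPTL4 at -1.03 were also lower. Of 9202 genes, 14 were at least 2-fold higher and 13 at least 2-fold lower. Both probes of CHKA (1.17 and 1.24) and of XBP1 passed upward, and every probe of CXCR4, FAM13A and PFKFB3 passed downward. These genes were chosen after their values were seen.

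DDIT3, CHAC1 and PFKFB4 were the genes that changed linearly over the 4 times, 2 rising and 1 falling of 9771 tested. Each had 1 detected probe, so no second probe checks these trends. DDIT3 rose by 0.33 log2 units per hour (SE 0.0354, limma adjusted p = 0.0108) and CHAC1 by 0.37 (SE 0.0440, adjusted p = 0.0122), while PFKFB4 fell at -0.22 per hour (SE 0.0308, adjusted p = 0.0495), each from 4 arrays and 2 residual degrees of freedom. Below the threshold came the mitochondrial import gene GRPEL2 (adjusted p = 0.0630), CDC42EP2 (0.0836) and XBP1 (0.0866), with ATF3 and ADM at 0.114. Before adjustment, 696 genes had an unadjusted limma p under 0.05 with a rising slope and 705 with a falling slope, where chance gives 244.3 each. Shifts of single probes also separate the 6 h array from 0 h (unshared variance 0.135 of 0.183). The excess therefore need not be trends of genes. Without the intensity trend in the variance, 0 genes passed, with adjusted p = 0.0589 for DDIT3 and for CHAC1 and 0.172 for PFKFB4. Over that and the other alternatives fitted to 4 arrays the adjusted p ranged from 0.00054 to 0.0589 for DDIT3 and for CHAC1, and from 0.0160 to 0.172 for PFKFB4, and median scaling gave 17 rising and 5 falling genes. Leaving out 1 array leaves 1 residual degree of freedom. Then 6 genes rose and 5 fell without the 0 h array, where PFKFB4 had an adjusted p of 0.0663, 1236 and 1216 without the 2 h array, 27 and 12 without the 4 h array, and 0 and 0 without the 6 h array. With 1 array left out, the adjusted p ranged from 6.54e-24 to 1 for DDIT3, from 1.52e-23 to 1 for CHAC1 and from 2.13e-12 to 1 for PFKFB4, and the value of 1 came without the 6 h array. In the same fits the slopes moved far less. They ranged from 0.30 to 0.33 per hour for DDIT3, from 0.31 to 0.41 for CHAC1 and from -0.23 to -0.19 for PFKFB4. The adjusted p of these fits therefore does not follow the slopes and is no measure of their strength.

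Gene lists fixed before the data were examined gave a wider view, and 36 of 39 could be ranked. Standing apart means a median outside the central 95% of matched random lists. Lists of genes drawn independently would give this in 1.8 of 36 at each time. Members of a fixed list may move together and some lists share members, so 1.8 may understate what chance gives here. At 2 h 1 list stood apart upward and 2 downward, at 4 h 3 and 4, and at 6 h 4 and 6. List medians and means had opposite signs in 10 lists at 2 h, 4 at 4 h and 5 at 6 h, and 0 of these stood apart. Members named for their trend over a list, and not for their fold, were chosen after their values were seen. Where a list has no trend count, 0 of its members passed over the list alone and 0 over all genes. Rose and fell refer here to the sign of the fitted slope. Steps and shifts of single probes against the 0 h array enter this test too. Passing over a list alone therefore need not be a gradual change of the gene.

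The integrated stress response, through which ATF4 and CHOP induce genes of amino acid supply and stress signalling, had the highest list median at 6 h. Its 22 measured members had medians of 0.03, 0.28 and 0.80 at 2, 4 and 6 h (percentiles 71.0, 99.9 and 100), and at 6 h 15 were at least 1.5-fold higher and 0 lower. Against the 2 h array the 6 h median was 0.74 (percentile 100). By the limma trend, 13 members rose and 0 fell when adjusted over the list alone, and 2 rose over all genes. The 13 were ATF3, DDIT3, DDIT4, TRIB3, CHAC1, SESN2, SLC3A2, CEBPB, CEBPG, STC2, PPP1R15A, GDF15 and CTH. TRIB3, a pseudokinase that inhibits ATF4, went from 0.08 at 2 h to 0.82 at 6 h. CBS and VLDLR, chosen after their values were seen, stood below 0 at 6 h, at -0.45 and -0.17.

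**Figure D2:**
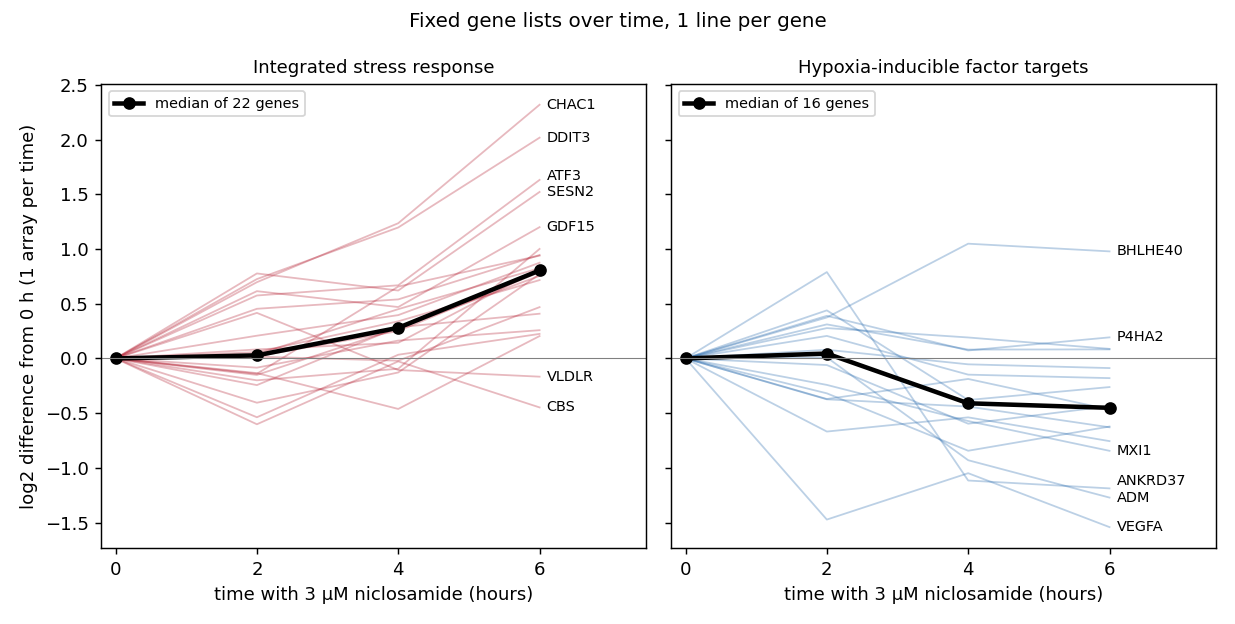
Log2 difference from 0 h (y axis) against hours with 3 µM niclosamide (x axis) for the 22 integrated stress response genes and the 16 hypoxia-inducible factor targets measured, 1 thin line per gene and 1 array per time, with the list median in black. The first median reaches 0.80 at 6 h, and the second lies at -0.41 at 4 h and -0.45 at 6 h.

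Amino acid and protein synthesis genes showed smaller differences. The synthesis of serine, glycine, proline and single-carbon units had medians of 0.07, 0.28 and 0.39 over 11 genes (percentiles 74.2, 99.0 and 99.5). PSAT1 and PSPH, enzymes of serine synthesis, stood at 0.74 and 1.04 at 6 h, although a second PSPH probe read -0.41, and SHMT1 and ALDH18A1 stood at -0.91 and -0.74, where the other 2 SHMT1 probes read -0.05 and 0.06. Against 2 h the 6 h median of the list was 0.26 (percentile 99.98). Adjusted over the list alone, PSAT1, PSPH and GOT1 rose and ALDH18A1 fell, against 0 genes over all genes. The second PSPH probe stood below 0 throughout, at -1.06, -0.73 and -0.41 at 2, 4 and 6 h. The 17 aminoacyl-tRNA synthetases, which charge tRNAs, had a median of 0.14 at 6 h (percentile 90.8) and 0.23 against 2 h (percentile 100), with CARS1 at 0.77, TARS1 at 0.67 and GARS1 at 0.65. TARS1 and GARS1 rose when adjusted over the list alone and 0 did over all genes. Targets of XBP1 and ATF6 in the unfolded protein response had a 6 h median of 0.03 over 16 genes (percentile 62.1), in which CALR stood at 0.96, HYOU1 at 0.76 and HSP90B1 at -0.68, and XBP1 rose when adjusted over the list alone, with 0 over all genes. Ribosome biogenesis (31 genes) and cytosolic ribosomal proteins (42 genes) had 6 h medians of -0.03 and -0.02 (percentiles 38.7 and 48.5), the first with 0.09 under median scaling, and DDX21 at 0.95 and RPL29 at -0.72 stood farthest out.

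Hypoxia-inducible factor targets went the other way. Their 16 measured members had medians of 0.04, -0.41 and -0.45 at 2, 4 and 6 h (percentiles 72.6, 0 and 0.02), and at 6 h 7 were at least 1.5-fold lower and 1 higher. Median scaling gave -0.28 at 4 h and -0.34 at 6 h, and against 2 h the 6 h median was -0.24 (percentile 0). ANKRD37 went from 0.79 at 2 h to -1.19 at 6 h, whereas VEGFA was already at -1.47 at 2 h and stood at -0.07 for 6 h against 2 h. The carbonic anhydrase gene CA12 stood at -0.76 and -0.77 on its probes, and BHLHE40, a transcriptional repressor that cellular stress also induces, was higher at 0.98. Adjusted over the list alone, VEGFA, ADM, ANKRD37, MXI1 and FAM162A fell and BHLHE40 rose, against 0 genes over all genes. For VEGFA, at -1.47, -1.05 and -1.54 at 2, 4 and 6 h, the slope is mostly a step against 0 h. Glycolysis and lactate export had a median of -0.02 over 21 genes at 6 h (percentile 45.1), 0.00 under median scaling, and -0.13 against 2 h (percentile 0.135). Within it the glucose transporter genes SLC2A1 and SLC2A3, ALDOC, PFKFB3 and PFKFB4 fell and 0 rose when adjusted over the list alone, of which PFKFB4 fell over all genes, while PKM stood at 0.96 and ENO2 at 0.58.

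Mitochondrial genes differed by smaller amounts. The 64 nuclear-encoded subunits of oxidative phosphorylation had medians of -0.00, -0.17 and -0.16 (percentiles 63.1, 0 and 0.17), of which the first was 0.03 under median scaling and the others -0.09 and -0.10, and against 2 h the 6 h median was -0.11 (percentile 0). NDUFS8, NDUFA8 and NDUFS7, subunits of complex I, stood at -0.77, -0.71 and -0.61 at 6 h, and 0 members passed the trend test over the list alone or over all genes. The tricarboxylic acid cycle with pyruvate dehydrogenase (20 genes) had a 6 h median of -0.04 (percentile 38.8), 0.04 under median scaling, with OGDH at 0.65 and SUCLG2 at -0.61. Mitochondrial biogenesis, import and proteostasis (20 genes) stood at -0.09 (percentile 20.7), with the import receptor gene TOMM22 at -0.92 and ESRRA at 0.76. Fatty acid oxidation (15 genes) was at 0.01 (percentile 56.0), fatty acid synthesis (12 genes) at -0.14 (percentile 13.4) and nucleotide synthesis (15 genes) at 0.08 (percentile 75.8), with the guanine nucleotide enzyme gene IMPDH1 at -1.22. Cholesterol synthesis and uptake (19 genes) was at 0.08 (percentile 73.5) and at 0.27 against 2 h (percentile 100), with SQLE at 0.74 and 0.24 on 2 probes and STARD4 at -0.64. In these 6 lists 0 genes passed the trend test over the list alone.

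Cell cycle lists had medians on both sides of 0. G1/S and DNA replication genes (22 measured) had medians of -0.32, -0.03 and -0.29 (percentiles 0.14, 25.4 and 0.55), where median scaling gave -0.24, 0.08 and -0.20, and against 2 h the 6 h median was -0.03 and did not stand apart. The list thus stood apart on the 2 h and 6 h arrays and not at 4 h. The shifts of single probes against 0 h were also larger at 2 h and 6 h, with unshared variances of 0.149 and 0.135. They were not absent at 4 h, where it was 0.0725. At 6 h CDT1 stood at -1.05, GINS2 at -0.99 and CDC45 at -0.76. G2/M and mitosis genes (34 measured) had medians of -0.18, 0.34 and -0.07 (percentiles 2.39, 100 and 24.9), and median scaling gave -0.07, 0.52 and 0.05, which turns the third. At 4 h 5 of them were at least 1.5-fold higher and 1 lower, with the APC/C activator CDC20 at -0.61 at 4 h and -1.18 at 6 h. Replication-dependent histones (8 measured), whose transcripts peak in S phase, had medians of -0.23, -0.53 and -0.35 (percentiles 8.09, 0 and 2.09), with -0.43 and -0.26 under median scaling at 4 and 6 h, and -0.23 at 6 h against 2 h (percentile 0.64), with H1-2 at -1.11 and H2BC5 at -0.85 at 6 h. H1-2 and H2BC5 fell when adjusted over the list alone, with 0 over all genes, and neither of the other 2 lists held a gene that passed.

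**Figure D3:**
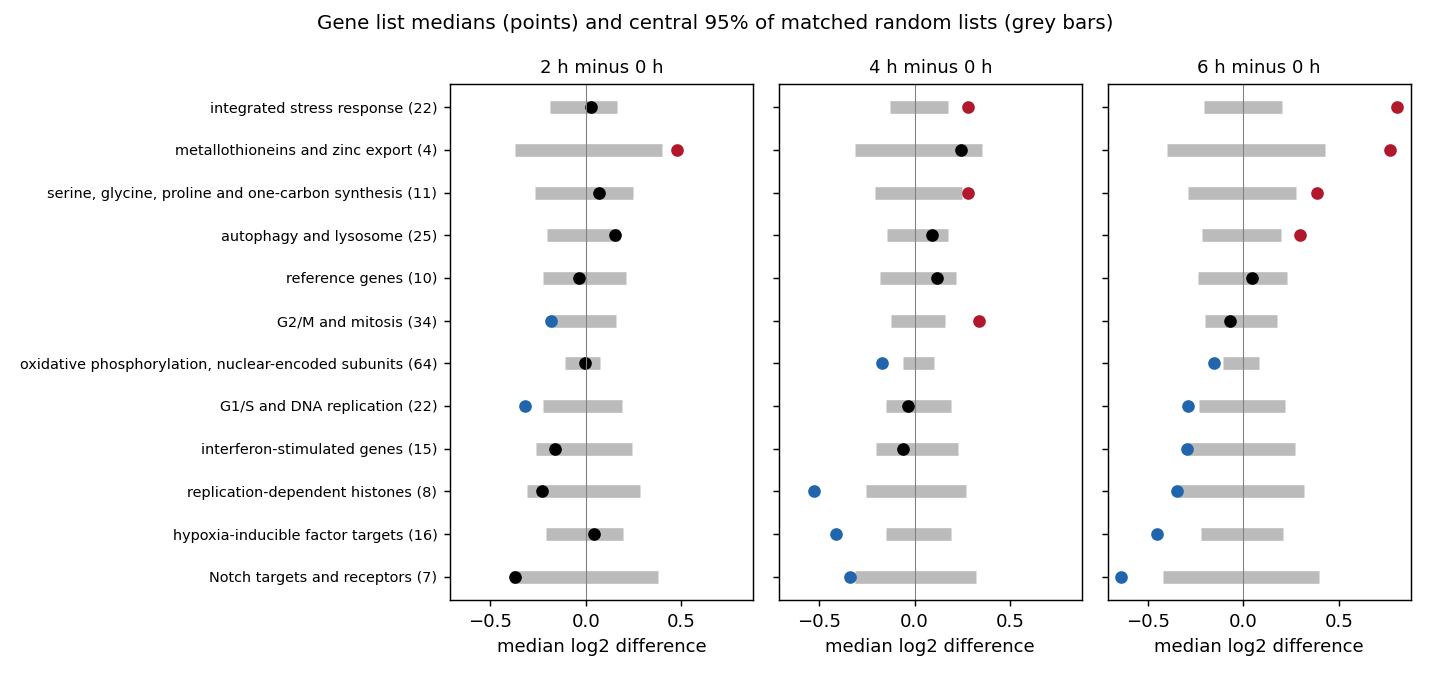
Median log2 difference from 0 h (x axis) of the gene lists that stood apart at any time and of the reference genes, with the number of measured genes in brackets, as points at 2, 4 and 6 h, with grey bars for the central 95% of 10000 matched random lists. Red points lie above and blue points below their bar. At 6 h the integrated stress response lies at 0.80 and the Notch list at -0.64. That Notch value is the brightest JAG2 probe, and a second JAG2 probe read 0.66.

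Signalling lists held members in both directions. Notch receptors and targets (7 measured) had medians of -0.37, -0.34 and -0.64 (percentiles 3.26, 1.73 and 0.13), with -0.22 and -0.53 under median scaling at 4 and 6 h, and -0.22 at 6 h against 2 h (percentile 1.07), with NOTCH3 at -0.81, HEYL at -0.66 and the ligand gene JAG2 at -0.64 at 6 h, where a second JAG2 probe read 0.66. The 6 h Notch median is itself that brightest JAG2 value, so it rests on a probe whose sign the second JAG2 probe does not share. Wnt and beta-catenin targets (10 measured) had a 6 h median of -0.17 (percentile 13.6) and -0.33 against 2 h (percentile 0). AXIN2 stood at -0.70, MYC at -0.66 with a second probe at -0.82, CCND1 at -0.30 and NOTUM at 1.06 with a second probe at 0.47, and BAMBI, at -1.10, fell when adjusted over the list alone, with 0 over all genes. STAT3 targets (14 measured) had a median of 0.02 (percentile 54.7) with members apart in both directions. PIM1 (1.34 at 6 h), BCL2L1 (1.02), FOS (0.94) and BCL6 (0.93) rose when adjusted over the list alone, and MYC and IRF1 fell. Over all genes 0 passed. IRF1 stood at -2.07, -1.25 and -2.26 at 2, 4 and 6 h, and BCL2L1 at 0.83, 0.70 and 1.02. Both are mostly steps against 0 h. STAT3 itself stood at -0.15 on its brightest probe and -0.14 and 0.10 on the others. NF-kappaB targets (7 measured) were at 0.14 (percentile 76.5), with TNFAIP3 at 0.84 and NFKBIE at -0.47. Immediate early genes (28 measured) were at 0.04 (percentile 68.7), with MAFF at 1.09 and its other probes at 0.92 and -0.27, and FOS and JUND rose when adjusted over the list alone, with 0 over all genes. Interferon-stimulated genes (15 measured) were at -0.29 (percentile 2.30), just past the limit of 2.5, at -0.18 under median scaling and at -0.21 against 2 h (percentile 0.14), with OAS2 at -0.79 and IFI27 at -1.04, which fell when adjusted over the list alone, with 0 over all genes. The 17 p53 targets were at 0.02 (percentile 64.1), with FAS at -0.52 and ZMAT3 at 0.66 on its brightest probe and -0.17 and -0.05 on the others.

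Lysosomal and metal-responsive lists had medians above 0 at 6 h. The autophagy and lysosome list of TFEB targets (25 measured) had medians of 0.15, 0.09 and 0.29 (percentiles 96.0, 83.6 and 99.8) and 0.15 at 6 h against 2 h (percentile 99.75). At 6 h 6 members were at least 1.5-fold higher, 2 lower and 17 neither, with the autophagy regulator UVRAG at 1.18, the lysosomal protease genes CTSD at 0.95, CTSL at -0.77 with other probes at -0.40 and -0.88, and CTSB at -0.83 with a second probe at 0.04. UVRAG and FNIP1 rose when adjusted over the list alone, with 0 over all genes. Metallothioneins and zinc export (4 measured) had medians of 0.48, 0.24 and 0.77 (percentiles 99.0, 90.2 and 99.9) and 0.28 at 6 h against 2 h (percentile 99.3), with MTF1 at 1.47 and the zinc exporter gene SLC30A1 at 0.91 on 1 probe and 0.50 on another. MTF1 and SLC30A1 rose when adjusted over the list alone, with 0 over all genes. NRF2 targets (16 measured), which respond to oxidants, were at 0.19 (percentile 96.9), with HMOX1 at 0.63 and SRXN1 at 0.72, and MAFG rose when adjusted over the list alone, with 0 over all genes. Antioxidant and glutathione enzymes (17 measured) were at -0.08 (percentile 22.1), with GPX4 at 0.51 and TXNIP at -0.29. Heat shock genes (16 measured) were at -0.04 (percentile 41.6), with FKBP4 at -0.88 and CRYAB at 0.65. The BCL2 family (10 measured) was at 0.02 (percentile 55.3), with the survival gene BCL2L1 at 1.02 and the death-promoting gene BIK at -0.98.

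Marker lists were ranked in the same way, and their values are differences over time rather than measures of cell identity. Of 20 tumour-initiating cell and pluripotency markers 9 were measured, with a 6 h median of 0.11 (percentile 77.1), and the reprogramming factor gene KLF4, at 1.03, rose when adjusted over the list alone, with 0 over all genes. ALDH1A1 stood at -0.19, with a second probe at 0.28, and ABCG2, CD44, KIT and PROM1 were not detected on any array. Epithelial markers (5 of 16 measured) were at -0.12 (percentile 32.7) with KRT19 at -0.70, and mesenchymal markers (4 of 12 measured) at -0.26 (percentile 7.60), in which S100A4, at -0.43 with a second probe at -0.28, fell when adjusted over the list alone, with 0 over all genes. Fibroblast markers, listed as those of another cell type, had 7 of 11 measured and were at -0.12 (percentile 28.9). Among markers of the remaining cell types, CD68 was the 1 leukocyte gene of 14 that was measured, at -0.22 on 1 probe and 0.18 and 0.55 on the others, EGFL7 and ESAM were the 2 endothelial genes of 10, at 0.36 and -0.21, and 0 of 7 erythroid genes were measured. The 10 reference genes had medians of -0.03, 0.12 and 0.05 (percentiles 41.8, 83.2 and 69.3), the first with 0.04 under median scaling, and POLR2A was at 0.64 at 6 h.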

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

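The tests of probe-specific shifts, of exchanged labels, of dim probes, of the 0 h array, of a processing batch and of the 6 h minus 2 h list medians were chosen after the results were seen.

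The G2/M and mitosis list had a median log2 difference from 0 h of -0.18 at 2 h (-0.1849) and of 0.34 at 4 h (0.3356), so these 34 genes had medians of opposite sign at neighbouring times. The 2 h percentile, 2.39, was just past the limit of 2.5, and under median scaling the medians were -0.07 and 0.52. The difference between the times was not tested, since each has 1 array. Probes without a name here also differed: 41 of 1891 detected on both arrays were at least 2-fold away from 0 h at 2 h, 11 of 1922 at 4 h and 63 of 1868 at 6 h. They take no part in the gene comparisons.

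In the part of the differences that the probes of a gene do not share, the 2 h and 6 h arrays resembled each other. Both differed in it from the 0 h array, with 4 h between. By the robust spread of all genes, 6 h lay about as near to 4 h (0.230) as to 2 h (0.215). Exchanged labels of the 2 h and 4 h arrays are argued against by the variance shared by the probes of a gene, which would be larger at 2 h and was smaller (0.0118, interval 0.00143 to 0.022, against 0.0340 at 4 h, 0.0284 to 0.0393), and noise of dim probes alone by r for 2 h minus 0 h of 0.114 (-0.0145 to 0.234) over the 400 genes with bright probes, against 0.735 for 6 h minus 2 h. A fault of the 0 h array alone is argued against too, since 2 h minus 0 h correlated on the same probe with 6 h minus 4 h, which does not use that array, at r = 0.506 (0.463 to 0.543), against 0.0123 between both probes of a gene (-0.047 to 0.068). Shifts of single probes rather than of genes have the values they need: r was 0.0735 for 2 h minus 0 h and 0.638 for 6 h minus 2 h, so many single-probe folds against 0 h may not be changes of the gene. The labels give no processing batch of 0 h and 4 h apart from 2 h and 6 h. Such a batch alone would make 0 h and 4 h alike in the unshared part. Their unshared variance was 0.0725, above 0.0538 for 4 h minus 2 h and 0.0382 for 6 h minus 4 h. This argues against the batch as the whole source. For 4 h minus 0 h with 6 h minus 2 h, r was 0.276 on the same probe (0.23 to 0.32). On the other probe it was 0.273 (0.225 to 0.317). That likeness cannot decide, since 6 h minus 2 h held little unshared variance (0.0218). A batch as part of the source stays open beside transcript isoforms and probe base composition, which were not tested here.

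Integrated stress response genes were higher at 6 h, with a median of 0.80. Shifts of single probes are argued against by the 6 h minus 2 h median of 0.741 (percentile 100), as those arrays are alike in the probe-specific part. Time in culture or handling rather than niclosamide cannot be told apart from the drug, since 0 arrays came from cells kept as long without it. An effect of niclosamide on the stress response therefore stays a hypothesis, untested against that explanation.

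Hypoxia-inducible factor targets were lower at 6 h, with a median of -0.45. Here too the 6 h minus 2 h median kept its sign, at -0.242 (percentile 0), against shifts of single probes as the whole source. Time in culture or handling rather than niclosamide cannot be told apart, again with 0 arrays of cells kept as long without the drug. A lower activity of the factor under niclosamide therefore stays a hypothesis as well.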

How the results depend on the processing

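Comparisons with only 2 arrays normalized together, with every one of several probes past the fold and with 6 h against 2 h were chosen after the results were seen. No paired analysis was possible because each time has 1 array, so the groups share fewer than 2 replicate numbers. Signal over background sets the floor: the lowest detected signal was 107 to 121 units against array medians of 62.4 to 66.0, so folds of dim genes are compressed and undetected genes give bounds. No list that stood apart and no named gene past 2-fold turned its direction, while 18 of 108 list medians turned sign under median scaling and 0 of these stood apart. For named genes this covers other scalings and the median over probes, not second probes taken alone. Second probes of SIPA1, UBE2J2, UNC119 and PSPH had the opposite sign at 6 h. By brightest probe, 27 genes with several probes passed upward at 6 h and 32 downward. Every probe had the same sign in 22 and 13 of these. No detection filter, detection on all 4 arrays, the median over probes and normalizing only 2 arrays left every fold count within 1.5 times. For the following the cause was not tested. Genes at least 2-fold higher and lower, which were 123 and 118 at 2 h, 20 and 39 at 4 h and 160 and 176 at 6 h, became 75 and 66, 7 and 18, and 101 and 94 without background correction. Median scaling gave 189 higher at 2 h, 66 and 14 at 4 h and 273 and 106 at 6 h, with 17 rising and 5 falling trends in place of 2 and 1. The processed values of the authors gave 75 lower at 2 h, 13 and 20 at 4 h and 106 lower at 6 h, and an offset of 50 gave 13 and 22 at 4 h. Genes with every one of several probes past the fold, a smaller set by construction, numbered 3 and 0, 0 and 0, and 8 and 2, and 6 h against 2 h gave 14 and 13. Trends numbered 0 and 0 without the intensity trend, 6 and 5 without the 0 h array, 1236 and 1216 without the 2 h array, 27 and 12 without the 4 h array, and 0 and 0 without the 6 h array. The hypoxia-inducible factor median at 6 h, -0.45, was -0.24 against 2 h, while that of the integrated stress response stayed between 0.74 and 0.87. Of 684 list medians under alternatives 41 moved by more than the spread of random lists, 26 of them under median scaling, and of 1300 named gene folds 104 moved by more than the yardstick.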

Other observations

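The comparison of list medians at 6 h with 2 h, the probe-pair correlations and the genes named in this part were chosen after the results were seen.

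Genes outside the fixed lists that differed between 6 h and 2 h included YPEL2, at 1.09 on the log2 scale, GCNT3, which encodes an enzyme that branches mucin glycans, at 1.10, and HSPBAP1 at 1.03. The mitochondrial co-chaperone gene GRPEL2 stood at 0.36, 0.92 and 1.37 at 2, 4 and 6 h. Lower at 6 h than at 2 h were INSIG2, which retains the cholesterol sensor in the endoplasmic reticulum, at -1.01, SPAAR, which encodes a lysosomal peptide, at -1.12, MAP6D1 at -1.07 and RASL11B at -1.03. Hexokinase 2, the first enzyme of glycolysis, read -0.97 and -0.56 on the probes of HK2 between those times.

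Lists that did not stand apart against 0 h at 6 h but did against 2 h were aminoacyl-tRNA synthetases (0.23, percentile 100), cholesterol synthesis and uptake (0.27, percentile 100), NRF2 targets (0.14, percentile 99.6), glycolysis and lactate export (-0.13, percentile 0.135), Wnt and beta-catenin targets (-0.33, percentile 0) and nucleotide synthesis (-0.13, percentile 1.17). G1/S and DNA replication genes, at -0.29 against 0 h, stood at -0.03 against 2 h, within the central 95% of random lists.

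Across the 1710 genes with 2 probes, and with genes not being independent replicates, the 2 h minus 0 h difference correlated with the 6 h minus 4 h difference, which uses none of the same arrays, at r = 0.506 on the same probe and 0.0123 between both probes of a gene. The 4 h minus 0 h difference correlated with 6 h minus 2 h at 0.276 on the same probe and 0.273 on the other probe (0.225 to 0.317). The 6 h minus 0 h difference correlated with 4 h minus 2 h at -0.219 on the same probe (-0.269 to -0.161) and 0.171 on the other probe (0.109 to 0.229). On the processed values of the authors r between probes was 0.0710 for 2 h minus 0 h and 0.654 for 6 h minus 2 h, on median scaling 0.0587 and 0.642, and without background correction 0.0705 and 0.658.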
